A study of Drosophila melanogaster with 28 samples.

How the data were processed

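Purified genomic DNA of BG-3 cells, a Drosophila line from the larval central nervous system, was assembled into chromatin in vitro for 5 h, per the labels' protocols. MSL2, CLAMP or a CLAMP mutant was added alone, or MSL2 was added together with CLAMP or the mutant, and bound for 30 min. The chromatin was then crosslinked, partly digested with MNase and immunoprecipitated with antibodies to MSL2, CLAMP or FLAG. The labels do not describe the mutation. They name 28 libraries in 12 groups, of which 9 groups received a protein (21 libraries) and 3 were negative controls (7 libraries, 1 group per antibody). The 3 groups with the MSL2 antibody had 3 libraries each and the other 6 groups with a protein had 2 each.

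The submitters' processing notes list Bowtie2 2.2.9, SAMtools 1.9 and HOMER 4.9 and the genome build dm6. The authors called peaks with HOMER findPeaks in its factor style on 1 merged tag set per group, with the negative control of the same antibody as input, per the file headers. A peak had to reach 10-fold over that control and 4-fold over the surrounding 10000 bp, each with a Poisson p of 1e-04, at a false discovery rate of 0.001. Tag numbers were scaled to 10000000 for calling, the peak size was 150 bp and the minimum distance between peaks 300 bp, per the file headers. These filters kept between 0.171% and 4.72% of the putative peaks of a list. In each list most were removed by comparison with the negative control. For MSL2 alone these were 43962 of 44129 putative peaks, against 35 removed by the surrounding signal. A region absent from a list therefore lay under at least 1 filter, which is not a measured loss of signal.

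The deposited peak lists give positions, and their score column is 1 in every line, so it carries no measurement. Tag totals, tags in peaks and filter counts were read from the file headers. The order of the lines was not that of position. On X it followed the peak numbers HOMER had assigned, with Spearman correlations between 0.763 and 0.997 over the peaks of a list. What those numbers rank is not stated in the headers, so the first 50% of a list in file order is used only as an alternative chosen after the data were examined.

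Starts were converted to 1-based coordinates. A peak counted as found in another list if it overlapped a peak there by at least 1 bp (bedtools 2.31.1 and an independent count gave the same numbers). Shares carry exact (Clopper-Pearson) 95% intervals, which cover the counting error of peaks only. The limit printed for chromosome 4, where the count was 0, is 3 counts of the total instead. For each pair of lists the peaks of the first were placed at random 1000 times on their own chromosomes, with their own widths. All peaks were merged where they overlapped into 1098 regions. Because each group has 1 merged list, no replicate error exists for any value, and no p-value between conditions was computed. Fisher's exact test (two-sided) was used only to compare 2 classes of peaks within 1 list. It treats peaks as independent and says nothing of the spread between libraries. Lists made with the same antibody share their negative control, so part of an overlap between them may come from that control, and the random placements leave this out. The overlap code recovered 122 of 122 shared peaks planted in simulated lists of the lengths of the MSL2 lists without and with CLAMP. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

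Gene positions came from a RefSeq gene table of the dm6 assembly (Release 6 plus ISO1 MT), which gives each gene's start and end. The table gives no strand, exons or sequence. Promoter, untranslated region, exon and intron classes, GA repeats and enriched 8-mers, which were planned before the data were examined, were therefore not analysed here. The share of peaks overlapping a gene body was used in their place, against 100 random placements. Arm lengths were taken to the last base reached by a gene or a peak. X then makes up 17.6% of the arms 2L, 2R, 3L, 3R, 4 and X.

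Genes and regions were named by a rule set before the data were examined. It takes every region in or within 2 kb of the roX RNA genes, 7 genes of the dosage compensation complex and its partners, genes with well-known GA-repeat promoters (29 of the 30 listed were in the table, Hsp67Bb was not) and the replication-dependent histone genes. For each of 7 main comparisons it also takes up to 10 regions found in both lists and in either alone, and the 10 regions found in the most lists. As the score does not vary, regions were ranked by the number of lists, then width, then position, and named by the gene body they overlap or the nearest one. Ranking by the number of lists favours regions common to several antibodies. Alternatives were reciprocal 50% overlap, peak centres within 500 bp, X or autosome arms alone, lists cut to equal length, all contigs, merging of peaks within 500 bp and base pairs in place of peaks. A stricter score threshold was not possible because the score is constant.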

Results

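MSL2 is the DNA-binding subunit of the male-specific complex that raises transcription from the Drosophila X chromosome, and CLAMP is a zinc finger protein that binds GA-rich sequence and is known to assist it. The study asked how both proteins cooperate and compete for sites on chromatin reconstituted in vitro from the DNA of BG-3 cells. Peak lists covered 9 combinations of antibody and protein. The MSL2 antibody was used with MSL2 alone, with MSL2 and CLAMP and with MSL2 and the CLAMP mutant. The CLAMP antibody was used with CLAMP or the mutant, each with and without MSL2, and the FLAG antibody with CLAMP and with the mutant. Each list was called on the merged tags of 2 or 3 libraries, so values below have counting intervals but no replicate error.

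Adding CLAMP went with more MSL2 peaks, and adding MSL2 with more CLAMP peaks. The MSL2 antibody gave 132 peaks with MSL2 alone, 466 with CLAMP present (3.53-fold) and 226 with the mutant (1.71-fold). The CLAMP antibody gave 74 peaks for CLAMP alone and 429 with MSL2 (5.80-fold), and 38 for the mutant alone and 70 with MSL2 (1.84-fold). In the FLAG precipitation CLAMP gave 354 peaks and the mutant 224. Total tags ran from 3875205 for CLAMP with MSL2 to 26822838 for MSL2 alone. In 7 of the 10 pairs of lists made with one antibody, the list with more tags had fewer peaks. Peaks held 0.183% of the tags with MSL2 alone, 1.60% with CLAMP and 0.394% with the mutant. They held 0.0658% for CLAMP alone against 0.627% with MSL2, 0.0328% for the mutant against 0.0377% with MSL2, and 2.50% and 1.38% in the FLAG lists of CLAMP and the mutant.

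**Figure D1:**
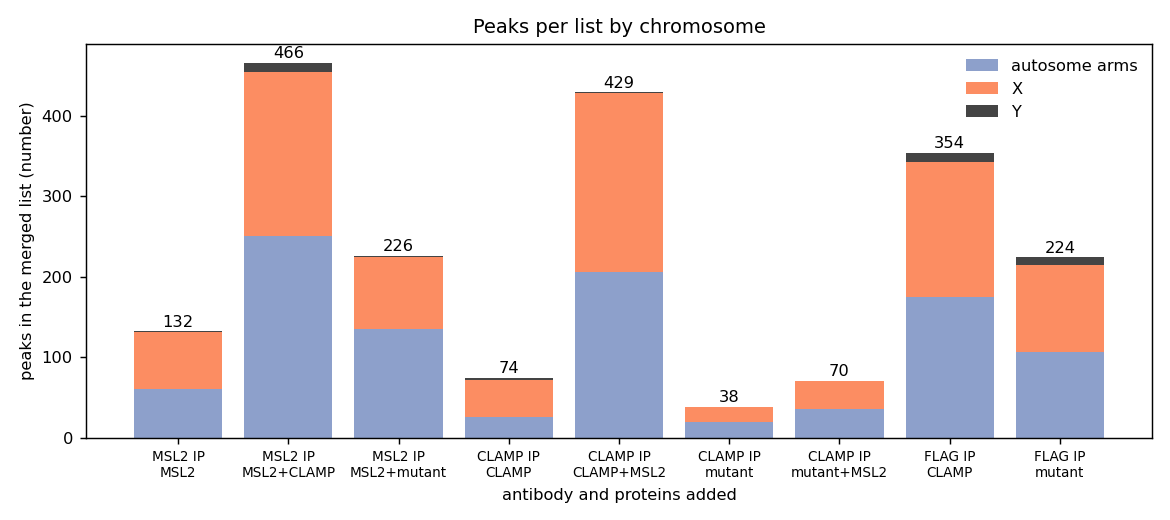
Number of peaks in each of the 9 merged lists, by antibody and added proteins, stacked by autosome arms, X and Y. MSL2 with CLAMP (466 peaks) and CLAMP with MSL2 (429) exceed the lists of either protein alone with the same antibody (132 and 74), and each list has 1 merged value without replicate error.

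The X chromosome held between 40.0% and 63.4% of the arm peaks of a list, where 17.6% of the arm length is X. The share was 54.2% for MSL2 alone (71 of 131, 95% interval 45.3 to 62.9), 44.7% with CLAMP (203 of 454, 40.1 to 49.4) and 40.0% with the mutant (90 of 225, 33.5 to 46.7). In lists without MSL2 it was 63.4% for CLAMP (51.1 to 74.5), 47.4% for the mutant (31.0 to 64.2), 49.0% for FLAG CLAMP (43.6 to 54.4) and 50.2% for the FLAG mutant (43.4 to 57.1). The share depended on the place in the list. In the first 50% of each list in file order it was 15.2% to 41.2%, with 17.6% inside the interval of 7 of the 9 lists, and in the second 50% it was 64.6% to 83.8%. Chromosome 4 held 0 of the 1084 arm regions, which allows a share of up to 0.277% (3 counts of the total), where 10.3 regions would lie there at its share of length. The excess of regions on X inflates this expectation, which was not recomputed without X.

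**Figure D2:**
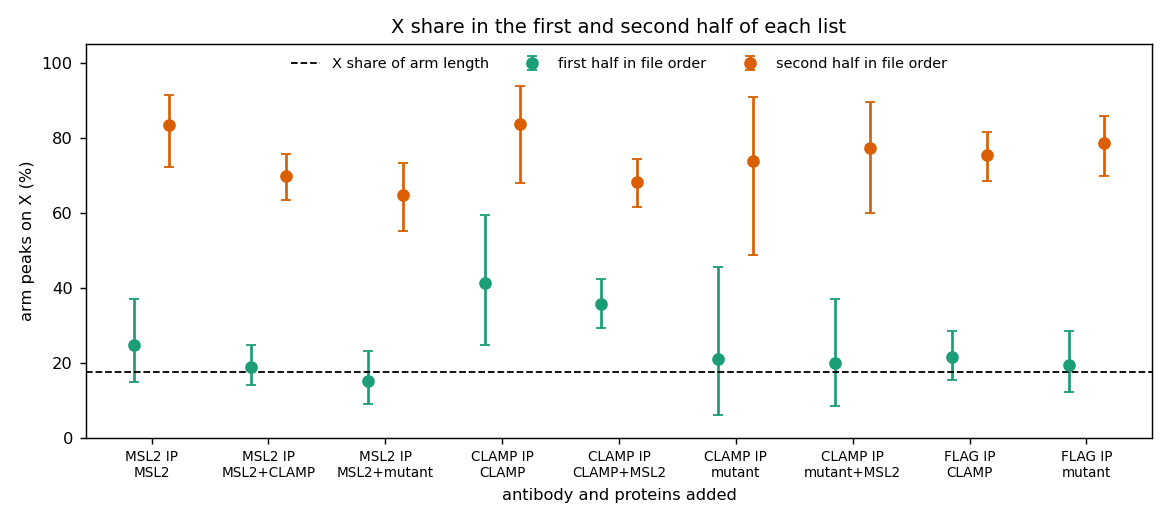
Percent of arm peaks on X in the first and second 50% of each list in file order, with exact 95% intervals, and the X share of arm length (17.6%, dashed). The second part lies above the first in 9 of 9 lists with separate intervals.

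With CLAMP present, MSL2 was found at nearly all of its own sites and at many more. Of the 132 MSL2-alone peaks, 122 were found again (92.4%, 86.5 to 96.3), against at most 3 in random placements. The peaks found in both lists included regions in para, a voltage-gated sodium channel gene (X 16501627 to 16501850), in mei-P26, a regulator of germline differentiation (X 9174069 to 9174286), in Tomosyn, an inhibitor of synaptic release (X 12648221 to 12648423), in rsh (X 13039176 to 13039507), in bru2, an RNA-binding protein gene (2L 12366072 to 12366352), and in trh, a regulator of tracheal development (3L 378058 to 378273). Of the remaining 10 peaks, 9 lay in regions without any peak of the list with CLAMP, among them 2 in msl-2 itself and others in CG1695, CG15803, Slob, Tlk and Gs2. The list with CLAMP held 344 peaks not found with MSL2 alone. They included regions in Rbp6, an RNA-binding protein gene (3L 17159653 to 17159818), mamo, a zinc finger factor (X 13882417 to 13882611), Cow (3R 23074589 to 23074822), rdgA, a diacylglycerol kinase (X 9023360 to 9023590), and dnc, a cAMP phosphodiesterase (X 3325806 to 3326172). Of the 344 added peaks, 46 overlapped a FLAG CLAMP peak, 47 a peak of the CLAMP antibody in the same mixture and 95 an MSL2 peak of the mutant mixture. The added regions were 41.0% on X (136 of 332 on the arms, 35.6 to 46.5), against 54.9% (45.7 to 63.9) of the regions in both lists.

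With the mutant present, fewer of the MSL2-alone peaks were found again, 79 of 132 (59.8%, 51.0 to 68.3, at most 2 in random placements). Cutting the searched lists at random to 132 peaks gave 34.9% with the mutant and 26.2% with CLAMP, which follows by construction from the lengths of the lists and does not bear on their order. Peaks found again lay in Tomosyn, trh, CG42699 (X 5788778 to 5788984), Cph, a zinc finger factor (X 7154068 to 7154422), hiw, a ubiquitin ligase of synapses (X 15052062 to 15052333), and CG46320 (3L 5729092 to 5729375). Peaks missing with the mutant included those in para, mei-P26, CG34408 (X 10224687 to 10225024), rsh, bru2, acj6, a POU factor of neurons (X 15356656 to 15356836), Hk, a potassium channel subunit (X 10257615 to 10257784), and tei (2R 13629689 to 13629856). Another missing peak lay 165 bp from CG34386 (2R 18062020 to 18062250). New peaks with the mutant, 147 in number, included regions in Smr, a corepressor (X 12716089 to 12716261), Osbp (3R 24937537 to 24937697), SK, a calcium-activated potassium channel (X 5341579 to 5341824), and ninaE, the main rhodopsin (3R 19887605 to 19887813).

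The peaks missing with the mutant were mostly those at sites with a FLAG peak of the mutant, nearly all of which were also FLAG CLAMP sites, a split made after the data were examined. Of the 37 MSL2-alone peaks at FLAG mutant sites, 4 were found with the mutant (10.8%, 3.03 to 25.4), and of the 95 others 75 (78.9%, 69.4 to 86.6; Fisher's exact test, two-sided, p = 3.99e-13). With CLAMP in place of the mutant the same classes were found at 34 of 37 (91.9%, 78.1 to 98.3) and 88 of 95 (92.6%, 85.4 to 97.0; exact p = 1). Split by FLAG CLAMP sites instead, 5 of 40 (12.5%, 4.19 to 26.8) and 74 of 92 (80.4%, 70.9 to 88.0) were found with the mutant, so the split does not set mutant sites apart from CLAMP sites. The test compares peaks within merged lists, not libraries. Over whole lists, a FLAG CLAMP site lay under 30.3% of the MSL2-alone peaks (40 of 132, 22.6 to 38.9), 17.8% of those with CLAMP (83 of 466, 14.4 to 21.6) and 2.21% of those with the mutant (5 of 226, 0.722 to 5.09).

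**Figure D3:**
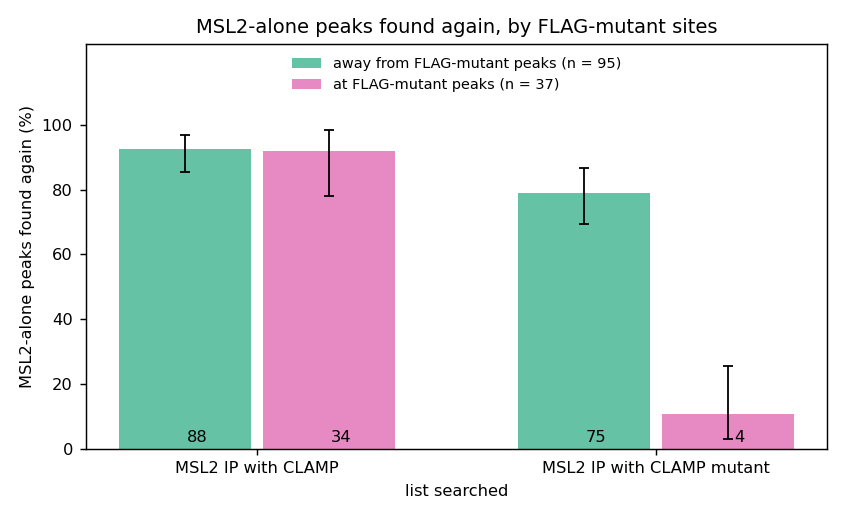
Percent of MSL2-alone peaks found again in the MSL2 lists made with CLAMP and with the CLAMP mutant, for peaks away from (n = 95) and at (n = 37) FLAG mutant peaks, with exact 95% intervals and the number found at the foot of each bar. With the mutant, 4 of 37 peaks at its sites were found and 75 of 95 elsewhere.

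Between the 2 mixtures, most MSL2 peaks found with the mutant were also found with CLAMP, and the list with CLAMP held many others. Of the 226 peaks with the mutant, 170 were in the list with CLAMP (75.2%, 69.1 to 80.7), which held 296 more. Of the 132 MSL2-alone peaks, 75 were found in both mixtures, 47 only with CLAMP, 4 only with the mutant and 6 in neither. The share of peaks found in one mixture only that were found with CLAMP was thus 92.2% (81.1 to 97.8). Regions only with CLAMP included para, mei-P26, Rbp6, rsh, bru2, mamo and acj6. Regions only with the mutant included 2 in msl-2 (2L 3463773 to 3464132 and 3464887 to 3465037), 1 in Clamp (2L 22166622 to 22166775), and others in para (X 16492364 to 16492624) and Slob (2L 7654030 to 7654239), a gene named for binding a potassium channel.

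With MSL2 present the list of CLAMP peaks was longer and held just over 50% of the peaks of CLAMP alone. With the CLAMP antibody, 41 of the 74 peaks of CLAMP alone were found with MSL2 (55.4%, 43.4 to 67.0, at most 2 at random), and 388 further peaks appeared. Peaks found in both lay in para, CG34408, mei-P26, Tomosyn, Rbp6, mamo, Him, an inhibitor of muscle differentiation (X 18210373 to 18210709), and nAChRalpha3, a nicotinic receptor subunit (X 8301326 to 8301507). Peaks only with CLAMP alone included those in asRNA:CR44894 (X 10195847 to 10196089), CG43902 (X 10170989 to 10171179), inaE (X 13784282 to 13784448), Ran (X 11144963 to 11145124) and, 1096 bp from the gene, upd3 (X 18285692 to 18285876). Those only with MSL2 included rsh, bru2, trh, CG42699, tei, Ca-alpha1T, a T-type calcium channel (X 6189523 to 6189884), mtd (3R 5282869 to 5283204) and eag, a potassium channel (X 14978961 to 14979236). All of these named regions were also in both FLAG lists, made without MSL2. Of the 388 further peaks, 119 (30.7%, 26.1 to 35.5) overlapped a FLAG CLAMP peak. All 10 CLAMP peaks at MSL2-alone sites were found with MSL2 (interval 69.2 to 100), against 31 of the 64 others (48.4%, 35.8 to 61.3). Peaks found in both lists were also rich in FLAG CLAMP sites, made without MSL2. Of the 41 such peaks in the list with MSL2, 33 overlapped one (80.5%, 65.1 to 91.2), against 41 of all 74 CLAMP-alone peaks (55.4%, 43.4 to 67.0). The split thus does not set MSL2 sites apart from sites found by another antibody. Of the 40 FLAG CLAMP sites at MSL2-alone peaks, the CLAMP antibody found 9 without MSL2 (22.5%, 10.8 to 38.5) and 33 with it (82.5%, 67.2 to 92.7). Away from MSL2 sites it found 32 of 314 (10.2%, 7.08 to 14.1) and 119 of 314 (37.9%, 32.5 to 43.5). The counts rose by a similar factor at and away from MSL2 sites, in a list 5.80-fold longer. No relative gain particular to MSL2 sites is therefore shown. These splits were also made after the data were examined, and the spread between libraries is not known.

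For the mutant, the lists with and without MSL2 had little in common. Of 38 peaks of the mutant alone, 6 were found with MSL2 (15.8%, 6.02 to 31.3, at most 1 at random), and 64 others appeared. The 6 shared regions lay in para, Rbp6, Him, nAChRalpha3, Ran and 165 bp from CG34386. Among regions only without MSL2 were mei-P26, rsh, bru2, mamo, tei, shakB, an innexin (X 20916585 to 20916838), and fz2, a Wnt receptor (3L 19159495 to 19159719). Regions only with MSL2 included CG34408, CG1695 (X 20437029 to 20437243), 2 in msl-2, Sp1 (X 9744072 to 9744444), Paics (X 12760280 to 12760601) and Moe, which encodes moesin (X 8897295 to 8897494). Of these, the regions in CG34408, CG1695, Sp1 and Moe were also in the FLAG mutant list, made without MSL2. Those in msl-2 and Paics were not. At FLAG mutant sites under MSL2-alone peaks, the CLAMP antibody found 7 of 37 without MSL2 (18.9%, 7.96 to 35.2) and 4 of 37 with it (10.8%, 3.03 to 25.4), a difference within the intervals. Both lists held under 0.04% of their tags in peaks.

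In the FLAG precipitation, made without MSL2, nearly all peaks of the mutant were also peaks of CLAMP. There, 219 of the 224 mutant peaks overlapped a CLAMP peak (97.8%, 94.9 to 99.3, at most 4 at random), and these were 61.9% of the 354 CLAMP peaks (56.6 to 66.9). The 5 peaks only with the mutant lay in luna, Frq1 and SPR and, outside gene bodies, 4796 bp from pdm3 and 97098 bp from CR41519. The last lay close to a region of both FLAG lists (2L 23512857 to 23513007). With peak centres within 500 bp counted as shared, 4 peaks were only with the mutant. The 135 only with CLAMP included OdsH (X 17812322 to 17812609), dnc, CG46320, Sh, the Shaker potassium channel (X 18050827 to 18051029), mamo (X 13967746 to 13967936) and twi, the mesoderm factor Twist (2R 23046178 to 23046384). With the CLAMP antibody, 20 of 38 mutant peaks were found among the 74 of CLAMP (52.6%, 35.8 to 69.0, at most 1 at random). They included para, mei-P26, Rbp6, Him, mamo, nAChRalpha3, CG34353 (3R 27770730 to 27770896) and shakB. Among regions only with CLAMP were CG34408, Tomosyn, acj6, Hk, OdsH and dnc, and only with the mutant rsh, bru2, tei, rdgA, ush, a GATA cofactor (2L 490552 to 490847), and bi, a T-box factor (X 4420217 to 4420395). These differences hold for the CLAMP antibody only. The regions in CG34408, Tomosyn, acj6 and Hk were also in the FLAG mutant list, and those in OdsH and dnc were not. All those named as only with the mutant were in the FLAG CLAMP list.

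The lists of the CLAMP and FLAG antibodies overlapped in part. Of the 74 CLAMP-alone peaks of the CLAMP antibody, 41 were FLAG CLAMP peaks (55.4%, 43.4 to 67.0), and of 38 mutant peaks 22 were FLAG mutant peaks (57.9%, 40.8 to 73.7), with at most 2 at random in each case. In the first 50% of the CLAMP antibody lists in file order the shares were 89.2% and 84.2%. The CLAMP antibody lists had 0.0658% and 0.0328% of their tags in peaks, against 2.50% and 1.38% in the FLAG lists. In the mixture of MSL2 and CLAMP, 108 of the 429 peaks of the CLAMP antibody overlapped an MSL2 peak (25.2%, 21.1 to 29.6, at most 5 at random). The shared regions were 64.9% on X (55.2 to 73.7), against 47.3% (41.7 to 53.0) of those with the CLAMP antibody only and 38.2% (33.0 to 43.6) of those with the MSL2 antibody only. In the mixture of MSL2 and the mutant, 3 of 70 peaks overlapped an MSL2 peak (4.29%, 0.893 to 12.02), of which 2 lay in msl-2 and 1 in Clamp, with 0 elsewhere.

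**Figure D4:**
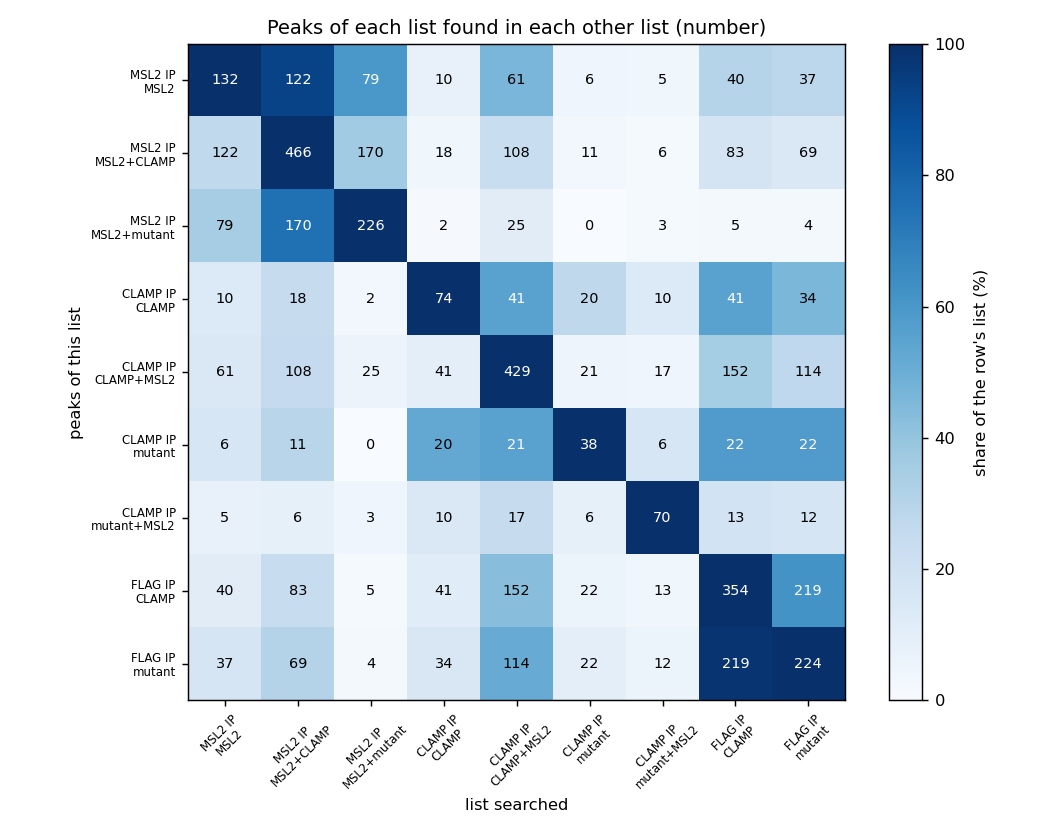
Number of peaks of each list (rows) that overlap a peak of each other list (columns) by at least 1 bp, shaded by the percent of the row's list. The FLAG lists share 219 peaks, and the MSL2 list made with the mutant shares 5 with FLAG CLAMP and 4 with the FLAG mutant.

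In all, 493 of the 1098 regions were found in at least 2 lists and 605 in 1 list. The 2 regions in 8 lists lay in para (X 16501627 to 16501850) and 165 bp from CG34386 (2R 18062020 to 18062250), and both were absent only from the MSL2 list made with the mutant. Those in 7 lists lay in Tomosyn, mei-P26, CG34408 and Rbp6 and in a gene-poor stretch of 3L (10737375 to 10737576), 34349 bp from CG43245. Regions in 6 lists included Him, rsh and 1 region 4666 bp from CG33664 (X 6379190 to 6379554).

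Among the genes listed beforehand, roX2, 1 of the 2 noncoding RNA genes of the dosage compensation complex, held 1 region (X 11580230 to 11580380), found with MSL2 alone, with MSL2 and CLAMP, and with the CLAMP antibody in that mixture. It was not in the mutant mixtures, and roX1 had no region within 2 kb. Random placement gave at least 1 region at these genes in 279 of 1000 draws. Of 7 genes of the dosage compensation complex and its partners, 3 had regions, 9 in all, against at most 3 at random. There were 5 in msl-2 (2L 3462218 to 3466112) and 3 in Clamp (2L 22165720 to 22169143), and 1 lay 825 bp from mof, the acetyltransferase of the complex (X 5872789 to 5873015), found with MSL2 in both mixtures. That region overlaps the body of another gene, GAA1. The genes msl-1, msl-3, mle and JIL-1 had none. The msl-2 and Clamp regions lie in the genes of the added proteins. Without these genes, the other 5 had 1 region, and 346 of 1000 random draws gave as many (an alternative added after the data were examined). Those in msl-2 were called 15 times in the 5 lists of mixtures with MSL2 and 0 times in the 4 without. Those in Clamp were called 4 times, in 3 of the 4 lists with the mutant and in none of the 4 lists with CLAMP.

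Of 29 genes with well-known GA-repeat promoters, 3 had regions, 8 in all, against a mean of 3.34 at random, and 18 of 1000 random draws had as many. The homeobox gene en, which patterns segments, had 1 (2R 11527880 to 11528142), found with FLAG CLAMP, the FLAG mutant and CLAMP with MSL2. Another lay in Eip74EF, an ecdysone-response gene (3L 17608442 to 17608592), found only with the CLAMP antibody in the mixture of MSL2 and CLAMP. The other 6 lay in hth, a homeobox gene 132 kb long, in lists that held MSL2. The random draws were not repeated without hth, and whether a region lay at a promoter was not resolved. No heat-shock gene in that list had a region. The 111 replication-dependent histone genes had 0 regions, against a mean of 0.654 at random, which does not separate them from chance.

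Peaks of the MSL2 antibody lay in gene bodies more often than random positions. The share was 88.5% with MSL2 alone (81.8 to 93.4), 86.3% with CLAMP (82.8 to 89.4) and 83.6% with the mutant (78.1 to 88.1), where random placements gave means of 72.2%, 70.9% and 71.0% and at most 81.7%, 77.1% and 76.4%. For CLAMP with MSL2 it was 78.7% (74.6 to 82.5), above the random maximum of 76.4%. In the other lists it lay within the range of random placements, for example 73.2% for FLAG CLAMP (68.2 to 77.8) and 74.9% for the FLAG mutant (68.5 to 80.5). Whether a peak lay in an exon or an intron was not resolved.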

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

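The X share of each whole list was planned, and the split by FLAG mutant sites and the other tests in this part were chosen after the results were seen. Peaks on Y lie outside the arms used for the shares. Most came from 3 lists, with 12 for MSL2 with CLAMP, 11 for FLAG CLAMP and 9 for the FLAG mutant, against at most 3 in any other list. The counts were not set against the length of Y, so no excess is shown. The 14 Y regions include 9 that these 3 lists have in common, in or near kl-5, PRY, Ppr-Y, ORY, CCY and Su(Ste):CR42422, the last of which was in 5 lists. Of the first 20 peaks of the FLAG CLAMP list in file order, 18 were in the list of MSL2 with CLAMP and 8 in that of the CLAMP antibody in the same mixture, whereas of all 354 peaks 83 and 152 were.

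MSL2-alone peaks at sites of the FLAG mutant, nearly all of them FLAG CLAMP sites too, were mostly missing once the mutant was added. A shift of peak centres is argued against, since of the 41 MSL2-alone peaks centred within 500 bp of a FLAG mutant peak, 8 (19.5%) had a peak of the mutant mixture within 500 bp, against 81.3% of the others. Loss of weak peaks at the threshold stays open: in the first 50% of the MSL2-alone list the kept share was 21.1% at mutant sites and 85.1% elsewhere (Fisher's exact test, two-sided, p = 1.40e-06), but the headers do not state that file order follows peak strength. Occupancy of these sites by the mutant may keep MSL2 off and also stays open. In the mixture the CLAMP antibody found 4 of the 37 FLAG mutant peaks at MSL2-alone sites (10.8%, 3.03 to 25.4) and 8 of the 187 others (4.28%, 1.86 to 8.26), with intervals that overlap. This antibody could hardly show occupancy, since even without MSL2 it found 22 of all 224 FLAG mutant peaks (9.82%, 6.26 to 14.5). Another property of these sites, or 1 library of the merged lists, was not tested.

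X held more than its 17.6% of arm length in all 9 lists as a whole. A preference of MSL2 for X as the whole cause is argued against by FLAG CLAMP without MSL2, with 49.0% of its arm peaks on X. BG-3 is a male line with fewer copies of X than of the autosomes. If the negative control held the same DNA, fewer copies would lower X tags in it and in the precipitation alike. The fold over the control then gives no reason for more X peaks, though background on X was not measured. The same tag threshold held for all chromosomes of a list (54 tags for MSL2 alone), which would not favour X. All 9 lists had a higher X share in their second 50% in file order, with separate intervals. This split cannot show whether X peaks had fewer tags, since file order is not stated to follow peak strength. Fewer X copies could also lower the tags of X peaks whatever the cause of their excess. Fewer X copies thus give no account of the excess by themselves, and its cause stays open. A higher density of binding sequence on X was not tested, and the first 50% of 2 CLAMP antibody lists still lay above the length share (41.2% and 35.5%).

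Peaks inside msl-2 and Clamp, the genes of the proteins added, may come from coding DNA carried over with these proteins. For msl-2 the calls fit that, with 15 in the lists of mixtures with MSL2 and 0 in the 4 others. For Clamp, carry-over cannot be told apart from other sources, as all 4 calls came with the mutant and none with unmutated CLAMP alone or mixed. Binding of MSL2 to its own gene also stays open, since 5 calls came with the CLAMP antibody and MSL2 may be precipitated with CLAMP. In the mutant mixture, however, the peaks shared by both antibodies were those in msl-2 (2) and Clamp (1) and 0 elsewhere.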

How the results depend on the processing

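No paired analysis was possible because the libraries of each group were merged into 1 list before calling, which also rules out leaving out replicates. A stricter score was not run because the score is constant, and the planned sequence and promoter alternatives were not run for want of sequence and strand. File order and gene body settings, the setting without peaks in msl-2 and Clamp, and the split by FLAG mutant sites with all its settings were chosen after the data were examined. Of all values recomputed, 168 stayed within the interval of the main value (counts within 1.5 times) and 40 moved. Where no construction is named, the cause was not tested. Some of the 168 could not move by construction. These were X shares in base pairs, and lists without peaks in msl-2 or Clamp in the setting that leaves such peaks out. Depth ran from 3875205 to 26822838 tags per list, and its effect on which regions passed was not tested.

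X shares in the first 50% in file order fell to 24.6% (MSL2 alone), 18.8% (with CLAMP), 15.2% (with mutant), 41.2% (CLAMP alone), 35.5% (CLAMP with MSL2), 21.1% (mutant alone), 20% (mutant with MSL2), 21.4% (FLAG CLAMP) and 19.4% (FLAG mutant). All contigs and merged neighbours left all 9 shares within their intervals. Base pairs gave the same 9 shares by construction, since the arm peaks have the same width.

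Shared peaks with reciprocal 50% overlap fell to 85.6% (MSL2 alone in with CLAMP), 93.3% (FLAG mutant in CLAMP) and 20.7% (CLAMP antibody in MSL2 antibody, CLAMP mixture). The last was 30.6% on X and 18.9% on autosomes. Autosome values were 70.0% for MSL2 alone with the mutant, 69.2% for CLAMP alone with MSL2 and 73.1% for CLAMP alone in FLAG CLAMP. The overlap of both antibodies in the mutant mixture was 0% on X and 0% without peaks in msl-2 and Clamp. Cutting lists to equal length removes peaks by construction and gave 26.2% and 34.9% for MSL2 alone in the CLAMP and mutant mixtures, 36.4% for the mutant mixture in the CLAMP mixture, 9.55% for CLAMP alone with MSL2, 27.4% for mutant in CLAMP, 62.2% for FLAG mutant in FLAG CLAMP, and 11.6% and 10.3% for CLAMP and mutant in their FLAG lists. The first 50% in file order gave higher shares, 84.1% (mutant in CLAMP mixture), 78.4% (CLAMP alone with MSL2), 89.2% and 84.2% (CLAMP and mutant in FLAG) and 34.4% (both antibodies, CLAMP mixture).

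With reciprocal 50% overlap, lost peaks rose to 19 for MSL2 alone with CLAMP and to 15 for the FLAG mutant in FLAG CLAMP. MSL2-alone peaks away from FLAG mutant sites were then kept at 84.6% with CLAMP and 68.3% with the mutant, and at 87.2% with the mutant on autosomes; values at mutant sites stayed within their intervals. Extending gene bodies by 500 bp gave 89.6% (MSL2 with CLAMP), 82.9% (CLAMP with MSL2) and 78.1% (FLAG CLAMP).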

Other observations

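Several long genes held clusters of regions. Of 596 genes with at least 1 region, 56 had 3 or more, and 42 of these were on X. Sh, the Shaker potassium channel gene, and mamo, a zinc finger factor, each had 11 regions over 139 kb and 144 kb. mgl had 10 over 142 kb and shakB, an innexin gene, 9 over 166 kb. Tomosyn also had 9 but in 21.8 kb, with at least 1 in each of the 9 lists. The 8 regions of Eip75B, an ecdysone-induced nuclear receptor, were the most of any autosomal gene. In the mixture of MSL2 and CLAMP, the CLAMP antibody found 5 of them and the MSL2 antibody 2. Regions on the arms were already 44.0% on X where found in 1 list and 49.2% where found in 2 or more. Neither this excess nor gene length was corrected for, so no clustering particular to X is shown.

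Some lists had hardly any regions of their own. Of the 132 regions of MSL2 alone, 2 were in no other list, and of the 224 of the FLAG mutant, 3. In contrast, 49 of the 70 regions of the mutant with MSL2, 206 of the 429 of CLAMP with MSL2 and 179 of the 466 of MSL2 with CLAMP were in 1 list only. Regions in 1 list were 44.0% on X (265 of 602 on the arms, 40.0 to 48.1), and those in 2 or more 49.2% (237 of 482, 44.6 to 53.7). Of the 388 peaks that CLAMP gained with MSL2, 178 (45.9%, 40.8 to 51.0) overlapped a list of another antibody, against at most 6 at random, and of the 344 that MSL2 gained with CLAMP, 73 (21.2%, 17.0 to 25.9), against at most 4.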
